A study of Mus musculus with 4 samples.

How the data were processed

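Single cells of dissociated MC38 tumours, enriched for tumour-infiltrating immune cells on Percoll, were captured on a DNBelab C droplet platform per the labels' protocols. Labels name 4 samples, a cDNA and an oligo library for wild-type mice and the same for FOXP3 humanized mice. The cDNA libraries were analysed, and the oligo libraries were not used here. The deposited matrices hold raw UMI counts per gene and barcode, written by PISA 1.0 per the file headers, with gene symbols and barcodes as lists. The submitters' processing notes name the genome build GRCm39. The aligner, annotation and rule for calling cells are not given in the sources used here, nor is which part of Foxp3 is humanized or how reads of that allele were counted. Each library's gene list held only genes with a UMI in it, and 22649 of 26172 genes were listed for both. No coordinates are given, because the reference annotation at hand is of another build.

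Cells with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept, which removed 6 wild-type barcodes and 0 humanized ones. Scrublet, run per library, marked 0 of 7691 wild-type and 1 of 11087 humanized barcodes, so doublet calling did not work. Cells with transcripts of more than one type were set aside by cluster instead. Counts were scaled to 10000 per cell and log-transformed. Both libraries were clustered together with Leiden at resolution 1 on 2000 variable genes, 30 principal components and 15 neighbours, without integration and without Foxp3. Clusters with at least 3 fixed T cell markers among their 50 leading genes were subclustered on 1000 genes and 15 components. Leading genes were those with the highest fold of mean level, with a pseudocount of 0.5 counts per 10000, among genes detected in 15% of the cluster's cells. A subcluster was named from at least 3 fixed markers among its 50 leading genes, with no more markers of another class than of its own among the top 10.

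Several of these choices were made after the clusters were seen. The leading genes were first ranked with a pseudocount of 0.1 among genes detected in 10% of cells. Under that ranking subcluster 1 had 0 Treg markers and 1 marker of another class in its top 10 genes, and could not have been compared as Treg-like. The reported ranking was then chosen with this outcome in view, so the name Treg-like for subcluster 1 is not an independent result, and the first ranking is given as an alternative. The other choices made then were to set aside as mixed any subcluster whose median level of 50 non-immune genes was over 30% of that in non-immune cells, to leave unnamed a subcluster with markers of another class beside 1 or more CD3 UMIs per cell, to leave out a subcluster with under 0.1 CD3 UMIs per cell, and to compare top 10 markers in naming. A rule for CD4 T-like cells tried at that point was dropped, because subclusters 3 and 5 were shallow and had no CD4 T cell marker among their top 10 genes. Clustering was moved to double precision so that it repeats on other processors, which left the reported subclusters as they were but changed some alternatives. The planned CD8 T-like, non-Treg CD4 T-like and macrophage-like classes were not found. Their place was taken by the other T-like cells, a choice also made afterwards. Median UMIs of T-like cells were 1798 in the wild-type and 1557 in the humanized library, against 15368 and 11575 over all barcodes.

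Raw UMIs were summed per class and library. Treg-like sums held 99278 wild-type and 102256 humanized UMIs, and those of the other T-like cells 159804 and 208201. A level is given as CPM, the count scaled to the UMIs summed over all genes, with an exact Poisson interval, a share with an exact binomial (Clopper-Pearson) interval, and a log2 ratio of humanized over wild-type with an exact conditional interval, all at 95%. A sum of 0 was set to a floor of 3 counts in a ratio. With 1 library per genotype no test was made and no p-value is given, and genotype cannot be separated from library or mouse. Genes were named by a rule fixed before the data were examined. Among genes listed for both libraries with at least 100 UMIs over both sums, those at least 2-fold apart with an interval excluding no difference were ranked, up to 15 each way in Treg-like cells and 5 in other T-like classes. Lipid, chemokine and MHC genes of non-immune cells, a comparison added later, were picked from its lists and from its ranking. Mitochondrial, ribosomal protein, predicted, receptor segment, haemoglobin and sex-linked genes were left out of the ranking. Foxp3 and its neighbours were always reported. Of 36 fixed gene lists, members with at least 20 UMIs were counted as 1.5-fold higher or lower. For lists with at least 5 such members, the median was placed among 10000 random lists matched on expression in 20 bins.

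On simulated Treg-like sums with 200 changed genes, the rule ran on 259 genes. It recovered 4 of 11 measured genes changed 2-fold, 10 of 10 changed 4-fold and 18 of 18 changed 8-fold, and called 0 of 220 unchanged genes. In 100 simulations of Treg-like sums without any change, over 17 lists, the number outside percentiles 2.5 to 97.5 had a median of 1 and a maximum of 4. All simulated sums were Poisson draws from the pooled profile, with no spread between cells or libraries. They therefore give no rate of false calls for the real sums. Alternatives were other cell filters, doublets kept, separate clustering, other resolutions, Foxp3 kept in clustering, a gate on UMIs, other scalings including TMM factors of edgeR 4.0.16, thinning to 1000 UMIs per cell and other UMI minimums. Those added after seeing the data were the first ranking, 5 other random seeds, subcluster 1 alone, leaving out the top cell of each gene, and genes at least as high in Treg-like as in non-immune cells. The gate took cells with a CD3 UMI, no CD8 UMI and UMIs of at least 2 of 5 Treg markers, Ctla4 among them. It set aside no mixed cells. Software was Python 3.11.15, scanpy 1.11.5, igraph 0.11.9, scipy 1.17.1 and R 4.3.3.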

Results

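The series profiled single cells from MC38 tumours, a mouse colon carcinoma line grown in wild-type mice and in mice with a humanized FOXP3 gene. FOXP3 is the transcription factor that defines regulatory T (Treg) cells, and the stated question was how Treg cells inside the tumour differ in expression between the genotypes. Mice were 10 weeks old and tumours were taken on day 20. Each genotype had 1 cDNA library of cells isolated as tumour-infiltrating immune cells, so n = 1 per genotype throughout, and no difference has a replicate check. The wild-type library held 7691 barcodes and 134214718 UMIs, with a median of 15368 UMIs per barcode. The humanized library held 11087 barcodes and 147738781 UMIs, with a median of 11575. The lowest barcode had 1001 UMIs in each library. Intervals below are 95% intervals that cover counting error only.

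Most cells in both libraries carried almost no leukocyte transcripts, although the labels describe immune cells. One cluster of the joint clustering was T-like, with 6 of the fixed T cell markers among its 50 leading genes, including Cd3g, Trbc1 and Trbc2. The cells outside it, called non-immune here, made up 98.3% of kept wild-type cells (98.0 to 98.6%) and 97.7% of kept humanized cells (97.4 to 98.0%). Ptprc, which encodes the pan-leukocyte protein CD45, had 147 UMIs in all kept wild-type cells and 217 in all kept humanized cells. Cd8a had 0 UMIs in the wild-type and 1 in the humanized library, and no CD8 T-like, CD4 T-like or macrophage-like class could be named. Among the 15 non-immune clusters, some were led by cell cycle genes such as Top2a and Cdc20, by metallothioneins Mt1 and Mt2, by collagens such as Col3a1, or by interferon-induced genes such as Gbp2 and Ifit3. Others were led by the chemokine genes Cxcl1 and Ccl2, by Apobec1, by Chac1, by Uqcrq, by the heat-shock gene Dnajb1, by Gm49313 or by Hnrnpf.

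T-like cells made up 1.37% of wild-type cells (105 cells, 1.12 to 1.65%) and 1.43% of humanized cells (159 cells, 1.22 to 1.67%). A further 20 wild-type and 78 humanized cells of the same cluster held T cell and non-immune transcripts together and were set aside as mixed. They were 0.26% (0.16 to 0.40%) and 0.70% (0.56 to 0.88%) of kept cells. That threshold was set after the clusters were seen. Subcluster 8, with almost no CD3 UMIs and led by Il1b, H2-Aa and Lyz2, was left out by a rule also set then, and was 0.052% of wild-type cells (4 cells) and 0.126% of humanized cells (14 cells). Gamma-delta T-like cells, led by Il17a, Trdc and Scart1, were 21.0% of wild-type T-like cells (13.6 to 29.99%) and 20.1% of humanized ones (14.2 to 27.2%).

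Treg-like cells formed 2 subclusters in a clustering without Foxp3. Subcluster 1 was led by Penk, Rgs16, Tnfrsf9 and Tnfrsf4, and also by Il1r2, a fixed neutrophil marker. Subcluster 6 was led by Klrg1, Izumo1r, Areg, Gzmb and Il10, and by Foxp3, which was counted but took no part in the clustering or naming. It had 1 Treg marker and 1 marker of another class in its top 10 genes, Areg being a fixed ILC2 marker, and subcluster 1 had 3 and 1. Both subclusters had 7 Treg markers other than Foxp3 among their 50 leading genes. Together they made up 36.2% of wild-type T-like cells (38 of 105, 27.0 to 46.1%) and 29.6% of humanized T-like cells (47 of 159, 22.6 to 37.3%), a difference within these intervals. Subcluster 6 held most wild-type Treg-like cells (20 of 38), and subcluster 1 held most humanized ones (37 of 47). The name of subcluster 1 depended on how leading genes were ranked. Under the ranking tried first it had no Treg marker in its top 10 genes, and subcluster 6 alone would be Treg-like, with a log2 ratio of shares of -1.60 (-2.86 to -0.44) in place of -0.29 (-0.94 to 0.36). Subcluster 6 was 19.0% of wild-type T-like cells (12.04 to 27.9%) and 6.29% of humanized ones (3.06 to 11.3%). Values of Foxp3 and of the genes named by size are therefore also given by subcluster. The median level of 50 non-immune genes was 14.6% of that in non-immune cells in subcluster 1 and 15.1% in subcluster 6.

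Foxp3 was lower in humanized than in wild-type Treg-like cells. It had 47 UMIs, or 473 CPM (348 to 630), in wild-type Treg-like cells and 9 UMIs, or 88.0 CPM (40.2 to 167), in humanized ones. The log2 ratio was -2.43 (-3.64 to -1.38). Subcluster 6 had 39 wild-type UMIs against 1 humanized UMI (log2 ratio -3.83, -9.17 to -1.27). Subcluster 1 had 8 UMIs in each library, and its log2 ratio of -0.74 (-2.35 to 0.87) was not distinguishable from 0 at this depth. The intervals of the subclusters overlap, so a larger difference in subcluster 6 is not established. A Foxp3 UMI was seen in 52.6% of wild-type Treg-like cells (35.8 to 69.0%, median 1647 UMIs) and 19.1% of humanized ones (9.15 to 33.3%, median 1500 UMIs). Thinned to 1000 UMIs per cell, with 0 cells too shallow, the shares were 26.3% (10 of 38 cells) and 12.8% (6 of 47). Thinned shares were also lower for Ptprc (39.5% and 21.3%) and Cd3e (47.4% and 38.3%), while those of Cd28, Ikzf2 and Il2ra were higher. The thinned shares alone therefore do not set Foxp3 apart from Ptprc. In non-immune cells, which should lack Foxp3 and have median depths of 15585 and 11709 UMIs, its unthinned shares were 0.251% and 0.240%. Among the neighbours of Foxp3 on the chromosome, Was had 10 and 11 UMIs in Treg-like cells (log2 ratio 0.095, -1.28 to 1.49). Ppp1r3f, Ccdc22, Pim2 and Otud5 had at most 6 UMIs in either library, and Cacna1f, Gpr173, Wdr13 and Kcnd1 had 0.

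**Figure D1:**
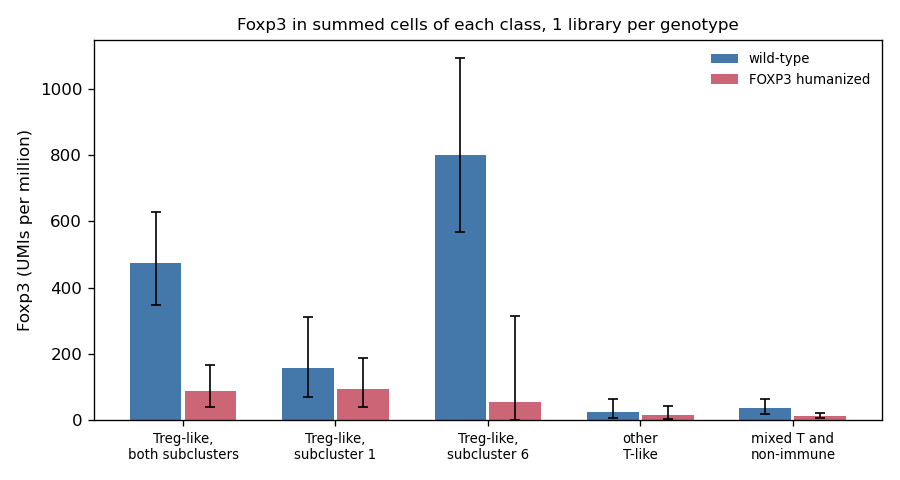
Foxp3 in CPM (bars) with 95% exact Poisson intervals (error bars, counting error only) in cells summed by class, for 1 wild-type and 1 humanized library. The bars for Treg-like subcluster 6 stand at 799.8 and 56.2 CPM, and those for subcluster 1 at 158 and 94.7 CPM.

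Few other genes in Treg-like cells met the rule of size. Of 257 genes with at least 100 UMIs over both sums, 3 were at least 2-fold higher and 5 at least 2-fold lower in humanized cells with an interval that excluded no difference. Higher were Nfkbia, the NF-kappaB inhibitor induced by that pathway (182 and 456 UMIs, log2 ratio 1.28, 1.03 to 1.54), the nuclear receptor gene Rora (1.18, 0.60 to 1.79) and the translation factor gene Eif4a1 (1.13, 0.51 to 1.78). Nfkbia was higher in both subclusters, with log2 ratios of 1.35 and 1.39, as was Rora (0.73 and 2.08). Eif4a1 was higher in subcluster 1 (1.18) and not in subcluster 6 (-0.35), and was at 842 CPM in non-immune cells. Lower were the chemokine gene Ccl5 (log2 ratio -3.74, -4.91 to -2.77), Arl6ip1 (-1.40, -1.99 to -0.83), Ptpn18 (-1.10, -1.63 to -0.59), AW112010 (-1.07, -1.53 to -0.62) and the predicted gene Gm10076 (-1.59, -1.92 to -1.27). A single cell held 77.0% of the Ccl5 UMIs, so that value rests on 1 wild-type cell, and Ccl5 was at -6.46 in subcluster 1 and 0.68 in subcluster 6. Ptpn18 was lower in subcluster 1 (-1.46) and not in subcluster 6 (0.022). Both subclusters had lower values of Arl6ip1 (-1.40 and -1.65), AW112010 (-0.74 and -0.94) and Gm10076 (-1.85 and -1.07), which was at 1842 CPM in non-immune cells. Without the cell with the most UMIs of each gene, only Nfkbia (1.18) and Gm10076 (-1.29) of these 8 genes still met the rule, and the UMI gate left only Arl6ip1 (-1.25). Over 19 alternatives Nfkbia met the rule in 18, Rora in 6 and Eif4a1 in 5, in part because fewer than 100 UMIs were left.

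Of 9 measured members of the Treg core list, 0 were at least 1.5-fold higher and 2 at least 1.5-fold lower, Foxp3 and Izumo1r, with a median log2 ratio of 0.31. Ikzf2, a Treg transcription factor gene, had 58 and 85 UMIs (log2 ratio 0.51, 0.010 to 1.02), Ctla4 had 90 and 116 (0.32, -0.086 to 0.74), and Il2ra had 27 and 36 (0.37, -0.39 to 1.15). By subcluster, Il2ra was at 1.41 in subcluster 1 and -0.55 in subcluster 6, Ikzf2 at 1.15 and 0.30, and Ctla4 at 0.71 and 0.32. Izumo1r, which encodes folate receptor 4, had 37 and 6 UMIs (-2.67, -4.20 to -1.41), with -2.33 in subcluster 1 and -2.19 in subcluster 6. Izumo1r was among the genes that lead subcluster 6, and the cells were clustered with it. In the list of effector genes of tumour Treg cells, 2 of 13 measured members were at least 1.5-fold higher and 6 at least 1.5-fold lower. Its median log2 ratio was -0.45, at percentile 2.61 of 10000 random lists matched on expression. Its lower members included Gzmb (71 and 24 UMIs, log2 ratio -1.61) and Klrg1 (36 and 15 UMIs, -1.31), which lead subcluster 6. Gzmb was at -0.91 in subcluster 1 and -0.50 in subcluster 6, and Klrg1 at 0.26 and -0.74. Its higher members were the chemokine receptor gene Cxcr6 (12 and 44 UMIs, 1.83) and Rora.

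Of the 36 fixed lists, 18 had at least 5 measured members in Treg-like cells, and the medians of 8 lay outside percentiles 2.5 to 97.5. Higher in humanized cells were resting T cell genes (5 of 5 members at least 1.5-fold higher, median 1.15), TGF-beta response genes (5 of 6, median 0.98), TNF and NF-kappaB targets (7 of 10, median 0.76), dissociation and heat-shock genes (10 of 18, median 0.65) and T cell receptor activation genes (3 of 8, median 0.45). Examples were Klf2 (11 and 51 UMIs), Ldlrad4 (5 and 26), Nfkb1 (14 and 36), Hspa1a (8 and 48, with 46.4% of the UMIs in 1 cell) and the early activation gene Cd69 (7 and 54). Klf2, Ldlrad4 and Cd69 had positive log2 ratios in both subclusters. Hspa1a had 7 and 14 UMIs in subcluster 1 (0.26) and 1 and 34 in subcluster 6, and Nfkb1 had 6 and 0 UMIs in subcluster 6. Klf2 was at 407 CPM in non-immune cells. The heat-shock list, a possible sign of cell handling, was higher together with the activation and NF-kappaB lists. It was higher in the other T-like cells as well (median 0.37), as were the NF-kappaB list (0.23), the TGF-beta list (0.63) and the resting list (0.31). The receptor activation list was not, with a median of -0.041 at percentile 62.1. In non-immune cells the heat-shock median was -0.0034 (percentile 96.3), with 21 of 23 members less than 1.5-fold apart. The subcluster mix of the other T-like cells also differed between the libraries and was not adjusted for. In subcluster 1 alone 10 lists had enough members and 6 lay outside, 3 of them among the 8, and the medians were 0.29 for heat-shock, 0.77 for receptor activation, 0.57 for NF-kappaB and -0.44 for oxidative phosphorylation genes. In subcluster 6 alone 8 lists had enough members and 2 lay outside, 1 of them among the 8, and the heat-shock median was 0.86. The resting and TGF-beta lists, and the cytotoxicity and apoptosis lists described below, had too few measured members in either subcluster alone. Their medians could therefore not be checked apart from the subcluster mix. Rgs16 of the TGF-beta list and Tnfrsf9 of the receptor activation list lead subcluster 1, which held most humanized Treg-like cells.

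Lower were cytotoxicity genes (4 of 5 members at least 1.5-fold lower, median -1.61), apoptosis and survival genes (4 of 5, median -0.76) and nuclear-encoded oxidative phosphorylation genes (9 of 30, median -0.43), for example Nkg7 (65 and 25 UMIs) and Cox7c (61 and 26 UMIs). The cytotoxicity median is the value of Gzmb, which leads subcluster 6, the one that held most wild-type Treg-like cells. Within each subcluster Gzmb was lower by less, as given above. The oxidative phosphorylation list names ATP synthase genes by older symbols, such as Atp5a1, where the matrices use newer ones, such as Atp5f1a. Those genes were therefore not matched, and even in non-immune cells only 32 of its 44 members were measured. Its values do not cover ATP synthase genes. The list was also lower in the other T-like cells (median -0.39), and in non-immune cells its median was -0.19, at percentile 0.08. The cytotoxicity list was lower in the other T-like cells too (median -0.38, percentile 0.745, 6 of 17 members at least 1.5-fold lower), while the apoptosis and survival list was at 0.14 there (percentile 85.2). The other measured cytotoxicity gene, Ccl4, was higher (20 and 56 UMIs, 63.2% of them in 1 cell). Of the list of CD8 T and NK cell markers, 2 of 2 measured members, Ccl5 and Nkg7, were at least 1.5-fold lower as well, and both are also cytotoxicity genes. Nkg7 had 32.2% of its UMIs in 1 cell and went opposite ways in the subclusters (-2.91 and 1.70). Under a gate on UMIs without clustering, which set aside no mixed cells, the cytotoxicity and receptor activation medians changed sign. The medians of the other 10 lists lay within those percentiles. They were Treg core 0.31, IL-2 and STAT5 targets 0.26, the unfolded protein response 0.19, glycolysis and hypoxia 0.14, suppressive mediators 0.066, costimulation -0.15, type I interferon -0.17, interferon gamma -0.32, tumour Treg effector genes -0.45 and myeloid genes -0.51.

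**Figure D2:**
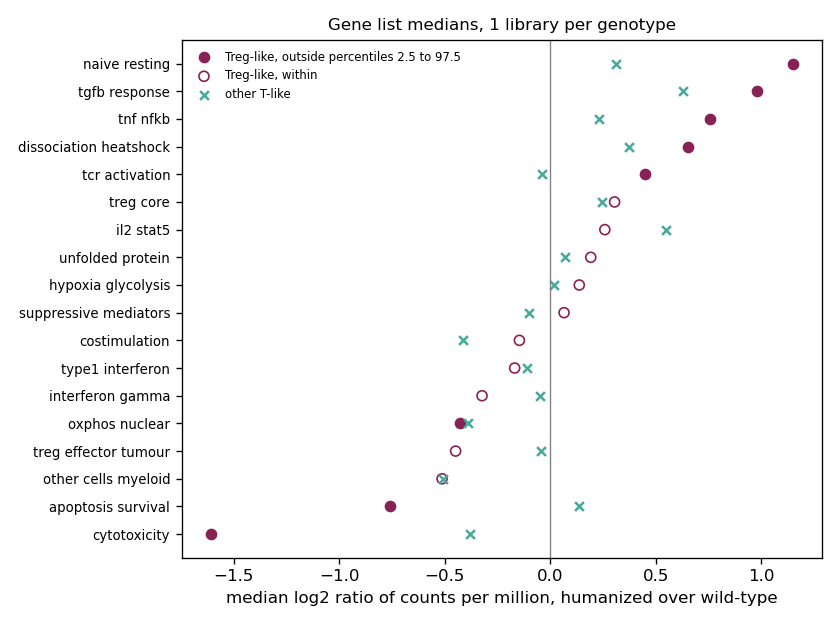
Median log2 ratio of CPM, humanized over wild-type, of each gene list with at least 5 measured members in Treg-like cells (circles, filled where the median lies outside percentiles 2.5 to 97.5 of matched random lists) and in the other T-like cells (crosses). Circles run from -1.61 for cytotoxicity genes to 1.15 for resting T cell genes.

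The other T-like cells, 67 wild-type and 112 humanized, were meant to show what the whole library shared, since the planned CD8, CD4 and macrophage classes were not found. They are gamma-delta T-like cells and unnamed subclusters 3, 4 and 5, in a mix that was not the same in both libraries. Subcluster 5, led by Bach2 and Tcf7 of the resting list, was 8.57% of wild-type T-like cells (3.99 to 15.6%) and 17.0% of humanized ones (11.5 to 23.7%). Subcluster 4, led by Ifng, Xcl1 and Ccl5, was 14.3% and 17.6%, and subcluster 3 was 20.0% and 15.7%. The mix was not adjusted for. Of 466 genes with at least 100 UMIs, 7 were at least 2-fold higher and 6 at least 2-fold lower in humanized cells by the same rule. Several rested on single cells. Ccl4 had 0 and 477 UMIs, 96.9% of them in 1 cell, Ccl3 had 0 and 151, 96.7% of them in 1 cell, and Ifng had 4 and 241, 58.4% of them in 1 cell. Il17a, the gamma-delta T cell cytokine gene, had 83 and 675 UMIs (log2 ratio 2.64, 2.31 to 2.99), and Ccl5 had 25 and 324 (3.31, 2.73 to 3.96), with 29.8% and 26.6% of their UMIs in 1 cell. Lower were Gzmc (504 and 13 UMIs, 40.6% in 1 cell), Tyrobp (-3.50, 41.4% in 1 cell), Ifitm2 (-1.28, 30.1% in 1 cell), Cox7c (-1.26) and Grcc10 (-1.18). The Treg-like median minus that of these cells was 0.84 for resting T cell genes, 0.53 for TNF and NF-kappaB targets and 0.28 for heat-shock genes. It was 0.49 for receptor activation, 0.35 for TGF-beta, -0.042 for oxidative phosphorylation, -0.90 for apoptosis and survival and -1.23 for cytotoxicity genes. The measured members were not the same in both classes, with 5 and 9 for the resting list. In 11 of 22 lists the median lay outside percentiles 2.5 to 97.5 here, so differences between the libraries were not limited to Treg-like cells.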

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

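All tests of the missing leukocyte transcripts and of Foxp3 were chosen after the result was seen. So were the Igkc tests on cells with under 10 of its UMIs, while those over all non-immune cells were chosen with its total and its highest cell known, but before the ratio and share they measure were seen.

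Most kept cells carried almost no leukocyte transcripts. Gene names out of step with the counts would scatter the fixed markers, and 6 T cell markers among the leading genes of 1 cluster argue against that. Host stromal cells would carry the Y-linked transcripts of T-like cells, but the upper bound of the ratio of non-immune to T-like CPM was 0.00113 for Eif2s3y and Kdm5d (8 and 32 UMIs), picked after the values of 4 Y-linked genes were seen, and Uty was at 0.136 and 33.4 CPM. Ddx3y, at 20.3 and 45.7 CPM, was lower in non-immune cells by far less and does not argue against host cells. So 3 of the 4 genes argue against host cells as most of these cells. Neither cells of the inoculated line nor a biological explanation was tested. Loss of small leukocytes at the minimum of 1000 UMIs stays open, since 41.3% of T-like cells (35.3 to 47.5%) but 1.43% of non-immune cells had under 1500 UMIs, and barcodes below the minimum were not analysed here.

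Foxp3 was lower in humanized Treg-like cells. Another mix of the subclusters is argued against as the whole cause, since the log2 ratio standardised over both was -2.05 (-3.49 to -1.12). An allele not counted at all would leave Foxp3 at background. The lower bound of Foxp3 in humanized Treg-like cells was 40.2 CPM, above the upper bound of 0.268 CPM in humanized non-immune cells. It was not above the upper bound of 42.1 CPM in humanized other T-like cells (3 UMIs in 1 cell), which are closer in depth. By these bounds the result thus depends on the background and does not decide. A Foxp3 UMI was seen in 19.1% of humanized Treg-like cells (9.15 to 33.3%) and 0.893% of humanized other T-like cells (0.0226 to 4.87%). These intervals are apart, so in this 1 library Foxp3 was seen in a larger share of Treg-like cells. An allele counted in part could give 1 common factor, and the intervals in subcluster 1, subcluster 6 and the mixed cells share log2 ratios from -2.35 to -1.27. A lower transcript level in humanized mice would give the same, so counting and genotype cannot be told apart here, and library and genotype are confounded.

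Igkc, the antibody kappa chain gene, stood out as a signal outside the compared cells, with 1862 UMIs in humanized non-immune cells against 3 in wild-type ones. A single cell with 1648 UMIs in all held 728 of them (39.1%), beside 419 Ighg2b UMIs, and the other 1134 (60.9%) lay in 1002 cells with under 10 each, which argues against a few expressing cells as the whole signal. Free RNA of the cell with the most Igkc (5129 UMIs) alone is argued against as the source of the rest, because the ratio of Igkc to other immunoglobulin and Jchain UMIs was 19.8 (17.5 to 22.5) in that cell and 10.2 (8.40 to 12.5) in non-immune cells with under 10 Igkc UMIs. The ratio over all non-immune cells, 3.38, decides nothing, because it includes the cell with 728, whose own ratio was 1.65 (1.47 to 1.87). Free RNA from more than 1 such cell may give a ratio between theirs and stays open, and no biological explanation was tested.

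Ctla4, a T cell inhibitory receptor gene, stood out for its level in non-immune cells, which the Treg-like comparison does not use, at 54.4 CPM in the wild-type and 76.0 CPM in the humanized library, where Icos was at 0.135 and 0.212 CPM.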

How the results depend on the processing

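Foxp3 was lower in humanized Treg-like cells under all 14 alternatives, and the Treg-like share was lower under all 14 of its own, with an interval that included no difference under 13 and lay below 0 under 1, the first ranking. The seeds, the first ranking, subcluster 1 alone, removal of the top cell and the limit to Treg-rich genes were chosen after seeing the data. The T-like share ratio kept within its interval under its 4 alternatives, and the lists in other T-like cells gave 11 outside under each of 3. Keeping doublets added only 1 cell, yet the clusters changed with it, as they did with the seed.

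Larger moves follow, for genes higher (3), genes lower (5) and lists outside (8). Under the first ranking, where the Treg-like class is subcluster 6 alone, the log2 share ratio was -1.60 (-2.86 to -0.44) and that of Foxp3 -3.83, with 1 gene higher, 1 lower and 2 lists. In subcluster 1 alone Foxp3 was at -0.74, with 5 genes higher and 3 lower. The UMI gate gave 8 higher and 27 lower. A UMI minimum of 30 gave 32 higher, 43 lower and 5 lists, a minimum of 500 gave 1, 0 and no list with enough members, and no minimum gave 123, 132 and 13 lists. Thinning gave 1 lower and 4 lists. Without the top cell of each gene 1 was lower. Lists numbered 5 with doublets kept and 3 with separate clustering. Seed 1 gave 3 lower and 3 lists, and seeds 2 and 5 each gave 8 lower and 4 lists. Fewer genes than 257 were tested under the first ranking (116), subcluster 1 (182), thinning (133), the minimum of 500 (75), seeds 1 (152), 2 (211) and 5 (216), kept doublets (236), separate clustering (224) and removal of the top cell (234). More were tested under the minimum of 30 (985), none (10889) and the gate (1826, over 76 wild-type and 110 humanized gated cells). Seeds 2 and 5 gave more lower genes from fewer tested, subcluster 1 more higher ones, and the cause was not tested there. Counts hide changes in the genes and lists called. With the mean over cells of counts per 10000, 8 lists lay outside, but only 5 of them were among the original 8. Under the gate 8 lay outside as well, and only 4 of them were among the original 8. Of the 3 higher genes the gate called 0, and each of the 5 seeds, separate clustering and removal of the top cell called 1, Nfkbia. Of the 5 lower ones the gate and removal of the top cell each called 1, seed 1 called 3 and the other seeds 5.

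The cytotoxicity median changed sign without a UMI minimum (0.54) and under the UMI gate (0.51), and the receptor activation median under the UMI gate (-0.047). The cause was not tested, and the gate is a weak check on Treg-like cells. Ctla4, a marker it used, was seen in 56.3% of wild-type and 58.9% of humanized non-immune cells, and mixed cells were not set aside. The gate moved the other medians towards 0, to -0.024 for apoptosis and survival, 0.25 for resting T cell genes, 0.33 for TGF-beta, 0.24 for NF-kappaB, 0.14 for heat-shock and -0.16 for oxidative phosphorylation genes. The heat-shock and oxidative phosphorylation medians kept their sign under 16 of 16 alternatives and the NF-kappaB median under 15 of 15. TMM shifted all ratios by 0.036. Cycling subclusters and a CD4 class were not found, so leaving out the first and a CD4 denominator were not run. No paired analysis was possible because each genotype had 1 library. Depth limits which genes enter, since 257 genes reached 100 UMIs and 1518 reached 20.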

Other observations

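The comparison of non-immune cells and that of gamma-delta T-like cells were added after seeing the data, and each rests on 1 library per genotype. Over 13822 genes with at least 100 UMIs in non-immune cells, the median log2 ratio of humanized over wild-type was -0.21, and the medians of matched random lists ran from -0.038 for oxidative phosphorylation to -0.45 for cytotoxicity genes. By the rule of size 16 genes were higher and 415 lower, 220 of the lower ones being predicted, ribosomal or similar genes. The lipid metabolism list had a median of 0.45, at percentile 100 of matched random lists, with 8 of 21 members at least 1.5-fold higher, 3 at least 1.5-fold lower and 10 between. Higher members were Insig1 (log2 ratio 0.77), Hmgcs1 (0.73), Idi1 (0.73) and Sqle (0.64), while Abca1, the cholesterol exporter gene, was at -0.76. Chemokine genes Cxcl1 (27.8 and 70.3 CPM, 1.34) and Ccl2 (112 and 195 CPM, 0.80) were higher. The TNF and NF-kappaB list was high only against matched random lists (median 0.047, percentile 100, random median -0.24). Of its 18 members 0 were at least 1.5-fold higher and 0 at least 1.5-fold lower. Cxcl1, Ccl2 and Nfkbia were among the leading genes of a cluster with 2 wild-type and 153 humanized cells, and Ccl2 also led one with 358 and 1568. Fdps of the lipid list was among the leading genes of the latter cluster. Values of non-immune cells are pooled over these differences in cluster mix. MHC class II genes were lower, with 5 of 8 members at least 1.5-fold lower, a list median of -0.62 at percentile 1.58, and H2-Ab1 at -1.28. In all, 12 of 30 list medians lay outside percentiles 2.5 to 97.5. Apobec1 (242 and 87.9 CPM) and Adam2 (115 and 34.6 CPM) were lower as well. Both led a cluster with 1404 wild-type and 410 humanized cells. They and Ccl2 were picked after their values were seen.

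The genes ranked first each way rested on single cells. Igfbp3 had 1 and 106 UMIs, 82.2% of them in 1 cell, and Krt18, a fixed tumour cell marker, had 159 and 2 UMIs, 90.1% of them in 1 cell. The next higher gene, Fam151b (14 and 114 UMIs, log2 ratio 2.89), did not, with 2.34% of its UMIs in its top cell.

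In gamma-delta T-like cells, 22 wild-type and 32 humanized, Il17a had 82 and 661 UMIs (log2 ratio 2.56, 2.23 to 2.91), and 30.4% of the UMIs were in 1 cell. Nfkbia was higher there as in Treg-like cells (74 and 254 UMIs, 1.33, 0.95 to 1.72), as were Jun (1.44), Gapdh (1.44) and Hspa8 (1.18). Of 9 lists with a median there, 4 lay above the upper percentile limit used for the other classes. The largest median was that of glycolysis and hypoxia genes (8 of 11 members at least 1.5-fold higher, median 0.87, percentile 99.99). The heat-shock list, a possible sign of cell handling, was higher as well (9 of 16 members at least 1.5-fold higher, median 0.63, percentile 99.99). The others were T cell receptor activation genes (median 0.69, percentile 97.7) and tumour Treg effector genes (median 0.41, percentile 98.5). Gapdh was at 1492 and 4037 CPM, Hspa8 at 995 and 2257 CPM and Jun at 628 and 1703 CPM, and in non-immune cells they were at 5263, 3025 and 635 CPM. Cmss1 was lower (-1.29). In non-immune cells Nfkbia was at 0.57 (0.55 to 0.58), so its difference between the libraries was not limited to T-like cells.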
